A study of Mus musculus with 6 samples.

How the data were processed

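The scanner files of 6 two-colour arrays were used. Per the labels, clone DNA was in the red channel (Cy5) and T lymphocyte DNA in the green channel (Cy3). The deposited log10 ratio of red over green had been background-subtracted and dye-normalised by the authors with Agilent Feature Extraction version 10.7.3.1, per the submitters' processing notes. The deposited intensity values were the processed signals of each channel, treated in the same way, and the raw median signals of spot and local background, per the file headers. Other deposited columns were flags of 0 or 1, set by the scanner software, for spots well above background, non-uniform, outlying or saturated. The arrays fell on 2 slides, which differed in export format per the file headers: C5, B11 and F1 had 110 columns, and G10, E7 and E2 had 42 and do not state the detrending settings. The authors' series matrix holds the same log10 ratios as the scanner files, with column medians of 0.0071 (C5), 0.0098 (B11), 0.0095 (G10), 0.0054 (F1), 0.0078 (E7) and 0.0092 (E2), so its scale and direction are known.

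Of 174305 features, those with a non-uniform or outlier flag were left out (115 in E7 to 185 in F1) and replicate spots were averaged, for 170305 probes. The green signal was well above background for 99.9% of probes on each array and the red signal for 99.6% (G10) to 99.8% (C5), and 169419 probes were well above background in both channels on all arrays. The log10 ratios were turned to log2 and each array's autosomal median was set to 0. Gene names on the array numbered 20749, of which 12789 were current symbols, 1808 older symbols and 6152 unmatched in the annotation used for names. Positions are those of the array's own build, NCBI37.

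The tests, thresholds, lists and the rule for naming genes were chosen before the data were examined. Each array was segmented by penalised least squares with a penalty of 40 in units of the noise variance and at least 5 probes, and segments past 0.25 were called. Gene ratios (mean over 3 or more probes) were tested against 0 with limma (lmFit and eBayes), with a Benjamini-Hochberg adjusted p under 0.05 and a mean past 0.25 for a call. These p-values measure only the spread between 6 clones of 1 line, and the reference's own spread is left out. Divergent segments came from segmenting each clone minus the median of the other 5 with at least 10 probes. Lists were tested by 10000 circular shifts of gene order and chromosomes by exact sign flips, both with Benjamini-Hochberg adjustment. Bins were 1 Mb wide.

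Genes were named as follows. Among limma calls on autosomes outside receptor loci with the same sign in 6 of 6 clones, the 12 highest and 12 lowest were taken, skipping any within 1 Mb of one taken before, plus called members of the fixed lists. Some genes that this rule takes are not reported here. For divergent segments, the 3 with the largest absolute mean per clone were taken, with their list members or the 2 genes with most probes. The lists were the major histocompatibility complex, antigen processing, ligands of co-stimulation and checkpoints, ligands of natural killer cells, interferon signalling, cytokines and suppressors, cell death, leukaemia genes, myeloid and lymphoid identity, and loci known to vary between stocks of the strain. Where probes were not well above background, clone signals were raised to the lowest well-above-background signal of the array, which makes the fold a lower bound.

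In simulated data, limma recovered 78% of genes changed by 0.3, 94% by 0.5, 78% by -0.3 and 100% by -1, with 4 false calls among 9123 unchanged genes. This simulation drew the noise of each array independently. In the real arrays, what is left of single probes after subtracting a running median correlated between clones with a mean r of 0.594. The simulated false calls therefore do not cover deviations that the arrays share. Segmentation at the scatter of the noisiest array found 90% of losses of 0.5 over 50 probes and 0% (0 of 60) over 10 probes, and at that of the quietest array 100% of both. Gains of 0.3 over 50 probes were found in 0% at the noisiest and 100% at the quietest array's scatter, and over 200 probes in 100% at each. Calls of short segments near the threshold thus depend on the array. The list test gave p under 0.05 for 5.8% of 400 random lists and for 99.8% of lists shifted by 0.5. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. The normexp alternative used an offset of 50 and the loess alternative a span of 0.3.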

Results

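Genomic DNA of 6 clones, each grown from a single cell of the mouse acute myeloid leukaemia line C1498, was compared with DNA of T lymphocytes of the same inbred strain, C57BL/6. Each clone (C5, B11, G10, F1, E7 and E2, replicates 1 to 6 of a single group) was hybridised once to a 2-colour tiling array that reads copy number along the genome. The red to green ratio of a probe gives the clone's copy number relative to the reference, so a log2 ratio of 0 stands for the typical copy number of the clone's autosomes. The arrays held 170305 distinct probes, 161460 of them on autosomes and 8723 on the X chromosome, with a median spacing of 10878 bp on the mouse build NCBI37 (mm9). The scatter between neighbouring probes ran from 0.118 log2 units in C5 to 0.349 in E2, and the number of arrays limits the precision of every mean below. The labels name genes involved in immunogenicity as the subject of the series but do not say which clones are more immunogenic, so the clones were treated as 1 group and no clone was set against another by outcome.

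The first question was which parts of the genome all clones had gained or lost relative to the normal reference. Taken clone by clone, segments past 0.25 log2 units covered a mean of 35.0% ± 3.55 of the autosomes (SD, n = 6), of which gains took 18.2% ± 1.68 and losses 16.8% ± 4.03. These shares are means over clones, and the share altered in all clones at once was not computed. At 0.25 the share ran from 31.0% in F1 to 40.7% in G10, but at 0.4 from 15.7% in B11 to 20.1% in C5. The order of the clones thus depends on the threshold. The lost share at 0.25 was highest in G10 (21.7%) and E2 (21.2%), whose arrays had the largest probe scatter. With the threshold at 0.4 the share was 17.4% ± 1.62, with 12.2% gained and 5.26% lost, and at 0.15 the gained share was 20.5% and the lost share 30.4%, so the balance of gains and losses depends on the threshold. At 0.25 with the ratios corrected for the base composition of the probes, an analysis chosen after seeing the data, the lost share was 11.2%. The mean profile of the clones held 48 gains and 22 losses of 1 Mb or longer past 0.4 on the autosomes, which came to 238.1 Mb and 105.2 Mb. Not every clone carried each of them: B11 was at 0.09 on chromosome 2 from 24.22 to 39.71 Mb, F1 at 0.05 on chromosome 3 from 50.71 to 52.37 Mb, C5 at -0.12 on chromosome 18 from 22.87 to 26.23 Mb and F1 at -0.24 on chromosome 16 from 57.13 to 69.84 Mb. The regions named in this paragraph and the next were picked after their values were seen, those just named because a clone differed and the others by length or by the list genes they hold. The longest losses were chromosome 17 from 76.38 to 95.25 Mb (log2 ratio -1.01 ± 0.03, SD, n = 6), and chromosome 14 from 64.24 to 77.93 Mb, with the tumour suppressor Rb1 (-0.92 ± 0.06). Chromosome 2 had lost the stretch from 134.4 to 140.1 Mb with the Notch ligand gene Jag1 (-1.14 ± 0.04) and the stretch from 172.8 to 179.5 Mb (-0.84 ± 0.05). On chromosome 18, the interval from 40.14 to 46.44 Mb lay at -1.03 ± 0.04. A loss on chromosome 4 from 87.68 to 89.64 Mb, which holds Cdkn2a, the gene of the cell cycle inhibitors p16 and p19, lay at -0.94 ± 0.05.

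Chromosome 1 from 50.49 to 65.31 Mb, which holds the apoptosis genes Casp8 and Cflar, lay at 0.51 ± 0.03 (SD, n = 6). Chromosome 5 from 120.4 to 122.5 Mb, with Ptpn11, which encodes the phosphatase SHP-2, lay at 0.74 ± 0.04, and the longer interval from 133.2 to 142.3 Mb on the same chromosome at 0.65 ± 0.04. Chromosome 4 from 122.2 to 131.2 Mb, with the T-cell kinase gene Lck, was at 0.64 ± 0.04. Chromosome 8 from 117.4 to 126.6 Mb, with Irf8, a transcription factor of myeloid differentiation, was at 0.62 ± 0.04. Chromosome 17 from 32.59 to 37.64 Mb, which holds the class II genes and the peptide transporter gene Tap2 of the major histocompatibility complex, was at 0.64 ± 0.04.

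**Figure D1:**
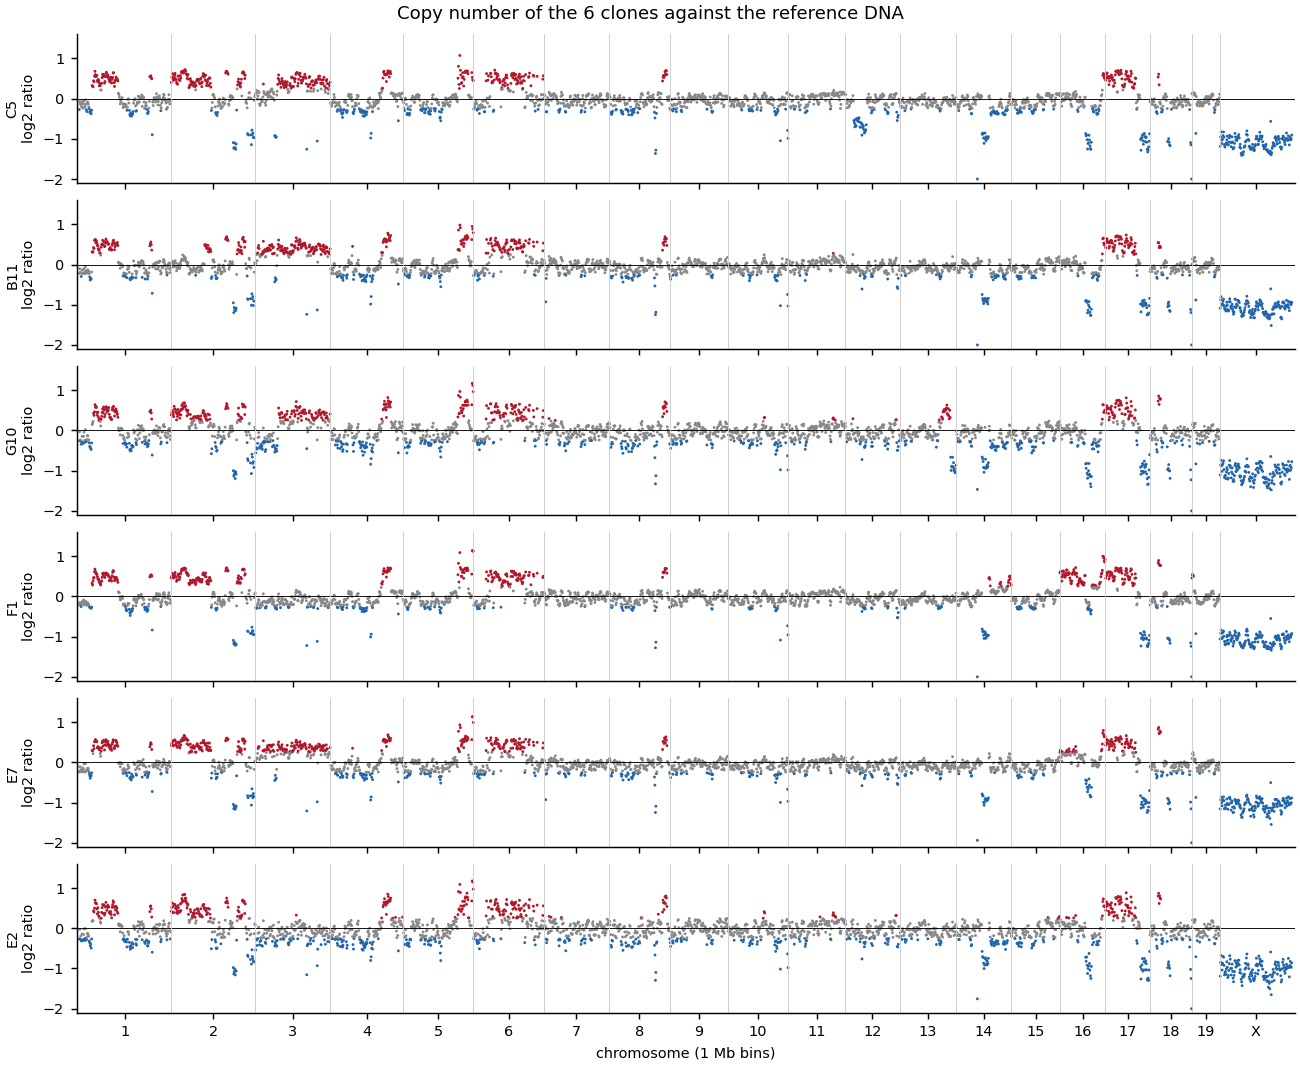
Median log2 ratio of clone over reference in bins of 1 Mb (y axis) along chromosomes 1 to 19 and X (x axis), 1 panel per clone, with bins above 0.25 in red and below -0.25 in blue; values beyond the axis range are drawn at its edge. The X chromosome lies near -1.04 in each of the 6 clones, and the gains and losses of chromosomes 1, 4, 5 and 17 recur across panels.

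At gene level, limma called 1933 genes gained and 1273 lost among 9323 genes with 3 or more probes, with 905 of the lost genes on autosomes. The gene with the highest ratio was Gpr56, an adhesion receptor of blood stem cells (1.31 ± 0.18, SD, n = 6, or 2.49-fold, limma adjusted p = 6.86e-07, higher in 6 of 6 clones). Ptpn11 lay at 1.19 ± 0.08 (2.28-fold), the splicing factor gene Sf3a3 at 1.19 ± 0.08, the beta-carotene oxygenase gene Bcmo1 at 1.30 ± 0.04 and 4930434E21Rik, an older name of Wdr95, at 1.31 ± 0.24. Among the other high genes were Tctn2 of the ciliary transition zone, the transcription factor genes Nfe2l3 (1.18) and Dmbx1 (1.03), the collagen gene Col8a2 (1.01), Sh3bgr (0.97), Stard13 (0.93) and Dtx2, a ubiquitin ligase of Notch signalling (0.93). Gpr56 lay in no region of 1 Mb or longer past 0.4, and the region around Ptpn11 lay at 0.74, under the ratio of the gene itself. These genes were taken for their high ratios and rest on few probes, 3 for Gpr56 and 6 for Ptpn11. Whether they carry smaller gains of their own was not tested.

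The lowest genes ranged from losses near the level of the X chromosome to pieces with little signal left in any clone. Probes of Tmx3, which encodes a thioredoxin-like protein of the endoplasmic reticulum, were in part not well above background in the clones, so the loss is given as at least 12.9-fold lower than the reference (limma adjusted p = 2.54e-06, lower in 6 of 6 clones). It sits in a stretch of chromosome 18 from 89.71 to 90.74 Mb with Dok6, an adaptor of receptor kinases. In the same way Immp2l, a subunit of a mitochondrial peptidase, was at least 2.70-fold lower over its 94 probes, with a core on chromosome 12 from 42.15 to 42.82 Mb that was at least 12.7-fold lower. The Notch coactivator gene Maml2 was at least 4.16-fold lower, Ext1, an enzyme of heparan sulphate synthesis, at least 2.85-fold, the actin-capping gene Capza2 at least 2.60-fold and Akap8l at least 2.22-fold. These are means over all probes of a gene. Maml2 held part of a segment of 5 probes at least 7.5-fold lower. Ext1, with 30 probes, held 2 segments of 5 probes each, at least 16.75-fold and 4.94-fold lower. For Capza2 1 of 3 probes was not well above background in any clone. For Akap8l 1 of 4 probes carried the loss, and over the probes well above background on all arrays its ratio was -0.23. A segment of 5 probes over Akap8 and part of Akap8l, on chromosome 17 from 32.43 to 32.47 Mb, was at least 6.48-fold lower. Entpd4, a Golgi enzyme that hydrolyses nucleotides, was measured above background throughout and was 4.10-fold lower (-2.04 ± 0.10, SD, n = 6). Tbce, a tubulin folding factor, fell by 1.38 on the log2 scale, Jag1 by 1.22 and the protease inhibitor gene Spink5 by 1.21. Esr2, the oestrogen receptor beta gene, was at least 5.93-fold lower in the mean of 6 clones (limma adjusted p = 0.0107), but the clones split on it, as described further below.

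The autosomal segments at or below a mean of -2 numbered 16 and covered 3.3 Mb. Besides those above, they touched Mbnl1, a splicing regulator, Stag1, a cohesin subunit, and Cpq, a peptidase. On the X chromosome, segments at this level lay in Tbl1x, in Brwd3 and in Sh3kbp1, an adaptor of receptor endocytosis.

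The lists fixed before the data were examined asked whether genes of immune recognition and of leukaemia were altered together. No list passed the circular shift test of gene order (0 of 8 lists after adjustment, 1 of 8 at an unadjusted p under 0.05, permutation, two-sided). Counts of called members adjusted over the list alone equalled those adjusted over all genes. Of 8 tested cell death genes, 4 were gained and 1 lost. The gained ones were Cflar, an inhibitor of caspase 8 (0.70 ± 0.14, SD, n = 6), Casp8 itself (0.53 ± 0.04), Bid, which links caspase 8 to mitochondria (0.58 ± 0.08), and the survival gene Bcl2l1 (0.56 ± 0.12). The lost one was Xiap, a caspase inhibitor on the X chromosome (-0.91 ± 0.07). The whole X chromosome lay at -1.04 ± 0.02, so this call shows no loss particular to Xiap. The median of the 7 autosomal members was 0.53 against a median of 0.03 over shifts (adjusted permutation p = 0.0840). Over the 15 autosomal members with 1 or more probes, a setting tested after seeing the data, the median was 0.14 (adjusted permutation p = 0.674).

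Of 6 tested antigen processing genes, 2 were gained, the peptide-loading chaperone gene Pdia3 (0.55 ± 0.13) and the lysosomal protease gene Ctss (0.39 ± 0.24), and 4 did not pass, such as Canx at 0.00 and Erap1 at -0.18 (adjusted permutation p of the list = 0.6998). Of the list of the major histocompatibility complex only Mr1, which presents vitamin metabolites, had 3 probes and it was gained (0.45 ± 0.09). Several genes of both lists on chromosome 17 had 1 or 2 probes and were not tested by limma. Their ratios were 0.74 for H2-T24, 0.51 for H2-Aa, 0.84 for H2-Ab1, 0.74 for Tap2, 0.61 for Tapbp and 0.69 for Psmb8, each above 0 in 6 of 6 clones. With genes of 1 or more probes, tested after seeing the data, the median of the 4 genes of the histocompatibility list was 0.63 and that of the 12 antigen processing genes 0.58, both with an adjusted permutation p of 0.129. In that setting 0 of 10 lists passed and 3 had an unadjusted p under 0.05.

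Of 9 tested ligands of co-stimulation and immune checkpoints, 2 were gained. They were Cd86, a ligand of CD28 (0.69 ± 0.15), and Vtcn1, an inhibitory ligand (0.38), which was above 0 in 5 of 6 clones and at -0.04 in F1. The other 7, among them Pdcd1lg2 (-0.05), did not pass (adjusted permutation p of the list = 0.6998). Cd40, the receptor through which helper T cells activate antigen-presenting cells, had 2 probes and lay at -0.95, inside a loss of chromosome 2 from 162.6 to 165.3 Mb (-0.83 ± 0.07, SD, n = 6). Of 2 tested ligands of natural killer cells, Clec2g was gained (0.42 ± 0.14) and Raet1a was not (0.06). The median of 3 genes of that list with any probe was 0.25 (adjusted permutation p = 0.672).

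Of 8 interferon signalling genes, 2 were gained, among them the receptor gene Ifnar2 (0.34 ± 0.20, SD, n = 6), and 6 did not pass, among them Jak1 (-0.09) and Jak2 (-0.13; adjusted permutation p of the list = 0.6998). Of 6 cytokine and suppressor genes, Vegfa, the vascular growth factor gene, was gained (0.71 ± 0.10), Tgfb2 was lost by a small margin (-0.26 ± 0.05) and 4 did not pass (adjusted permutation p of the list = 0.6998). The loss of Tgfb2 ended with the ratios centred on their mode (-0.24) or loess-normalised (-0.18), and the gain of Ifnar2 ended with loess (0.17). Of 4 genes of myeloid and lymphoid identity, Lck (0.63 ± 0.12) and Cd4 (0.33 ± 0.16) were gained and Pax5 (0.18) and Itgam (-0.01) did not pass (adjusted permutation p of the list = 0.561). The gain of Cd4 ended with loess (0.23) and with the base composition trend removed (0.21).

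Of 26 tested leukaemia genes, 5 were gained, 5 lost and 16 did not pass (median of the autosomal members 0.03, adjusted permutation p = 0.967). The gained ones were Ptpn11, the transcription factor gene Runx1 (0.66 ± 0.14, SD, n = 6), the chromatin genes Ezh2 (0.64 ± 0.11) and Asxl1 (0.57 ± 0.08), and Notch1 (0.56 ± 0.21). Rb1 fell by 0.98 on the log2 scale in the mean of 6 clones. Tet2, which oxidises methylated cytosine, lay at -0.98 ± 0.33, with -0.31 in G10 and values from -1.06 to -1.19 in the other 5 clones. Bcor (-1.05), Stag2 (-1.03) and Phf6 (-1.05) lie on the X chromosome, which as a whole lay at -1.04 ± 0.02. Their calls thus show no loss particular to these genes. Among those that did not pass were Nf1 (0.03) and Flt3 (-0.07). Of 6 loci known to differ between stocks of the strain, Entpd4 was lost, Wdfy1 gained (0.45 ± 0.06) and 4 did not pass, with a median of -0.05 (adjusted permutation p = 0.6998). Wdfy1 lies in a gain of chromosome 1 from 73.36 to 87.64 Mb (0.48 ± 0.02), so its call shows no gain particular to it. Entpd4 lies in the loss of chromosome 14 from 64.24 to 77.93 Mb (-0.92 ± 0.06), but its own ratio (-2.04) was lower. The list's mean over members was -0.31, carried by Entpd4.

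The antigen receptor loci were examined because the reference DNA came from T lymphocytes, whose receptor loci are rearranged. The T-cell receptor alpha/delta locus had a mean of -1.81 ± 0.42 (SD, n = 6) over 94 probes and the beta locus -1.65 ± 0.42 over 61 probes, in both cases below 0 in 6 of 6 clones. The loss was concentrated in 5 pieces at or below a mean of -2, on chromosome 14 between 54.16 and 54.82 Mb and on chromosome 6 between 41.08 and 41.48 Mb, where the clones' signal was at least 4.90-fold lower than the reference in the mean over 77 probes. The gamma locus on chromosome 13 lay at -0.49 ± 0.14 over 13 probes, with a piece from 19.25 to 19.3 Mb at least 1.83-fold lower. The immunoglobulin heavy locus lay at -0.23 ± 0.03, the kappa locus at 0.34 ± 0.06 and the lambda locus at 0.10 ± 0.25, or 0.01 without F1. Many probes of the lost pieces were not well above background in the clones, so with the clone signals raised to the background floor, an analysis chosen after seeing the data, the alpha/delta mean was -1.22 and the beta mean -1.07. With only probes well above background on all arrays, which leaves out most probes of the lost pieces, they were -0.36 and 0.15, and with normexp background correction -0.51 and -0.35. The gamma mean was -0.33, -0.00 and -0.15 in these 3 settings.

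**Figure D2:**
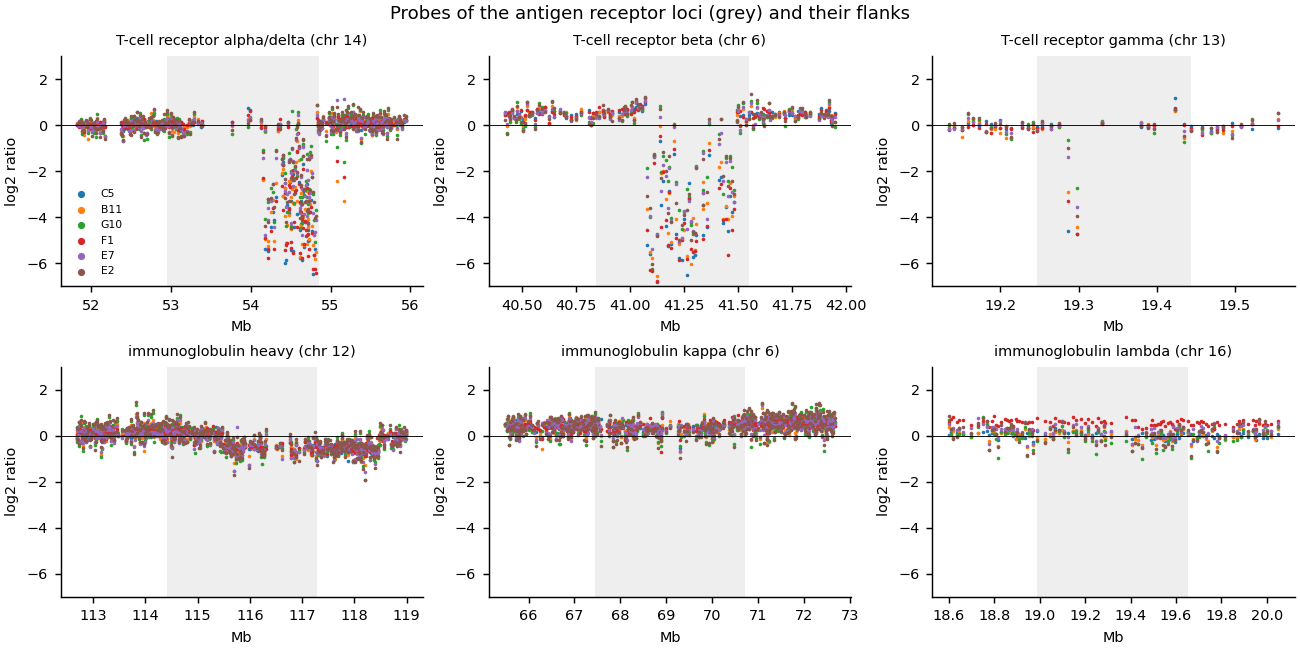
Log2 ratio of clone over reference (y axis) of single probes by position in Mb (x axis) in the 6 antigen receptor loci (grey) and their flanks, 1 colour per clone. Probes between 54.16 and 54.82 Mb on chromosome 14 and between 41.08 and 41.48 Mb on chromosome 6 lie below 0 in the 6 clones, and the kappa locus lies at 0.34.

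Whole chromosomes were compared by the clones' median ratios. Chromosome 17 lay at 0.35 ± 0.06, chromosome 6 at 0.24 ± 0.05 and chromosome 2 at 0.24 ± 0.13 (SD, n = 6), each above 0 in 6 of 6 clones. On chromosome 2, however, B11 was at only 0.006, against 0.198 to 0.346 in the other clones. The X chromosome lay at -1.04 ± 0.02, below 0 in 6 of 6. Chromosomes 17, 6, 2 and X and 11 further ones, 15 in all, reached an adjusted p of 0.0417 in the exact two-sided sign-flip permutation test, from the smallest p that 6 clones allow, 0.0313. The means of the other passing chromosomes lay between -0.10 (chromosome 18) and 0.03 (chromosome 1). The zero of each array is its autosomal median, so a small offset that the clones share can pass this test. These small means therefore do not show that whole chromosomes changed. With the ratios centred on their mode no chromosome passed (chromosome 17 0.37, adjusted exact permutation p = 0.0893, against 0.0391 to 0.0417 in the other processing settings), since several chromosomes must share the smallest p for any to pass. Probes of the Y chromosome were near background in both channels and gave no fold.

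The next question was how the clones differ from each other, asked of each clone against the median of the other 5, which cancels what the shared reference contributes. Summed over clones, so that an interval counts once for each clone it was found in, this gave 155 divergent segments, 39 of them 1 Mb or longer, and in 44 all clones were so far below the reference that background decides the difference. The deepest difference lay on chromosome 12 from 76.83 to 77.28 Mb, over Syne2, which anchors the nucleus, Esr2 and Sgpp1. Of its 51 probes 40 were not well above background in at least 1 clone, so the measured ratios of C5 (-5.68), B11 (-5.33) and E7 (-4.43) are limited by background. It was at -0.93 in G10, -0.98 in F1 and -0.98 in E2. The other segments that the naming rule takes, in Brwd3, Sh3kbp1 and Try10, lie among those decided by background. All regions in the next paragraph were picked after their values were seen, and a clone has no replicate array.

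In B11, the gain of chromosome 2 from 3.01 to 73.06 Mb that the other 5 clones carry (0.38 to 0.49) was absent (-0.06), and with it the gain of Notch1 (0.15 in B11). F1 and E2 lacked the gain of most of chromosome 3, with -0.08 and -0.07 from 47.23 to 109.9 Mb against 0.35 to 0.43 in the other 4 clones. The list genes on this arm are Vtcn1, Csf1, Nras and Ctss, and F1 had 0.13 and E2 0.06 for Ctss. For the others E2 lay at 0.20 (Vtcn1), 0.32 (Csf1) and 0.26 (Nras), and F1 at -0.04, 0.20 and -0.04, with 1 probe each for Csf1 and Nras. F1 was higher along the whole of chromosome 16 (0.41), where the other clones ran from -0.16 in G10 to 0.10 in E7. This chromosome carries 9 list genes, among them Cd80 (0.51 in F1), Cd86 (0.98), Cd200 (0.37), Cd47 (0.25), the class II regulator gene Ciita (0.60), Ifnar1 (0.57), Ifnar2 (0.65) and Runx1 (0.91). The distal part of chromosome 14 from 77.93 to 125.2 Mb lay at 0.25 in F1 and below 0 in the other 5. There E7 (-0.04) lay between F1 and the other 4 clones (-0.16 to -0.23). G10 alone gained chromosome 13 from 83.75 to 109.5 Mb (0.39) and lost the end from 109.5 to 120.3 Mb (-0.95) with Nnt, a mitochondrial transhydrogenase gene (-0.93 in G10). G10 alone kept chromosome 14 from 70.08 to 71.12 Mb (0.09), which holds the death receptor gene Tnfrsf10b (0.11 in G10) and lay between -0.72 and -0.90 in the other 5 clones. On chromosome 3 from 132.3 to 133.4 Mb, with Tet2, the ratio of G10 (-0.19) lay below that of its neighbouring segments (0.27 and 0.31), but less far down than in the other 5 clones (-0.95 to -1.12). C5 was lower than the other 5 clones on chromosome 12 from 21.54 to 51.71 Mb (-0.73 against -0.28 to -0.29), and C5 alone had lost an interval in Adk, the adenosine kinase gene (-0.87), and in the autophagy gene Atg7 (-0.80). F1 alone had lost an interval in the phosphatase gene Ppm1h (-0.99), and E2 alone had gained an interval with Ext2, a partner of Ext1 (0.72).

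**Figure D3:**
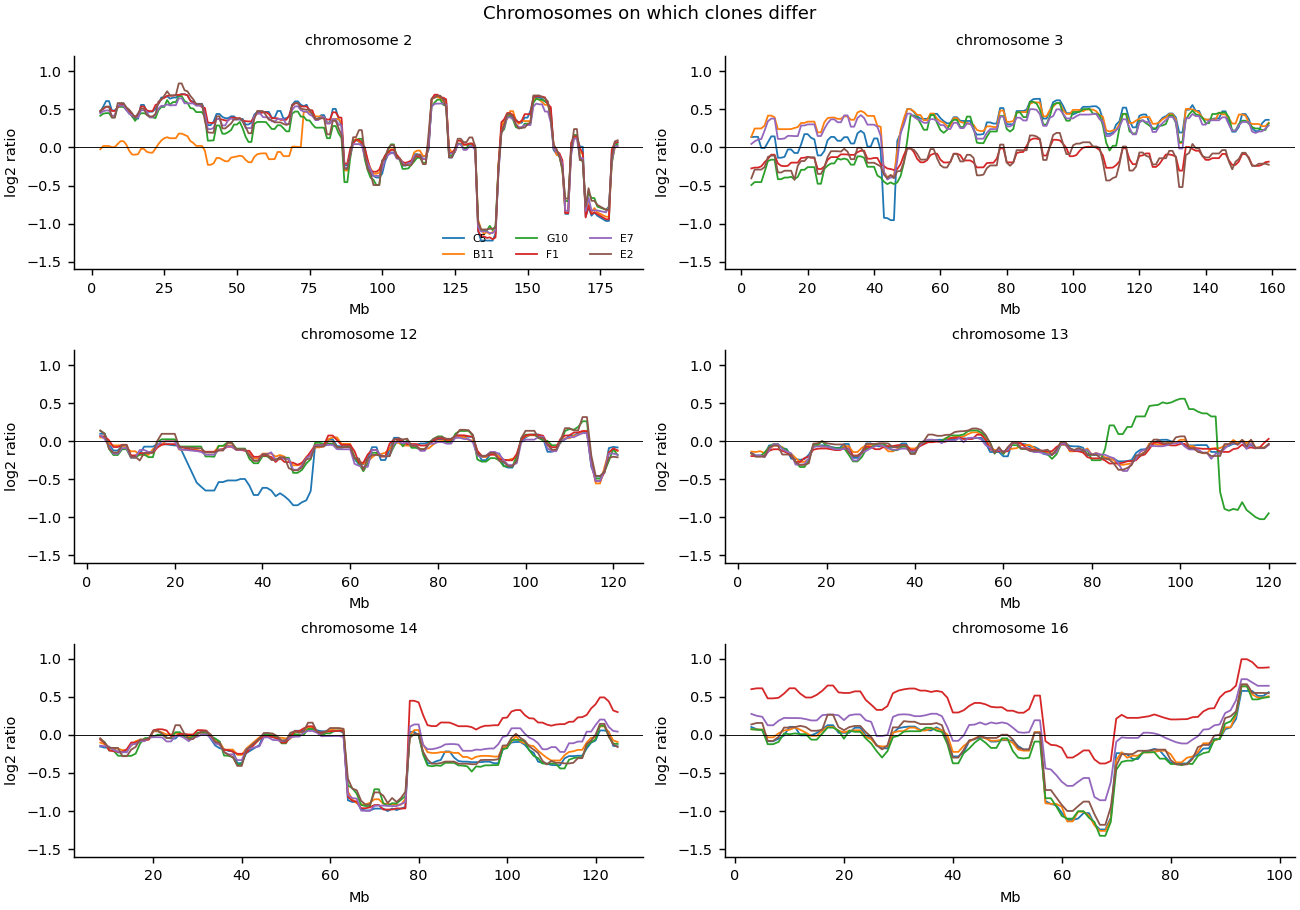
Median log2 ratio in bins of 1 Mb, smoothed over 3 bins (y axis), by position in Mb (x axis) on 6 chromosomes, 1 line per clone. B11 departs on chromosome 2, F1 and E2 on chromosome 3, C5 on chromosome 12, G10 on chromosome 13 and F1 on chromosomes 14 and 16. E7 lies between F1 and the other clones on chromosome 16 and on the distal part of chromosome 14.

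Several regions divided the clones into the same sets. C5, B11 and E7 were lower than G10, F1 and E2 over Syne2 and Esr2, and also in Bnc2 on chromosome 4 (C5 -0.26, B11 -0.26 and E7 -0.22, against G10 0.22, F1 0.39 and E2 0.19), in the kinase gene Cdk14 on chromosome 5 and in Trdn on chromosome 10. B11 and E7 were lower than the other 4 clones over Usp29 on chromosome 7 (B11 -0.94, E7 -0.88), in Csmd1 on chromosome 8 (-1.09 and -1.02, with -0.17 to -0.29 in the others) and in Trappc9 on chromosome 15 (-0.96 and -0.85), and shared a gain of chromosome 4 from 48.45 to 50 Mb (0.44 and 0.38). Across bins of 1 Mb, which are not independent replicates, the profiles of clone pairs correlated with a mean Pearson r of 0.893 (range 0.817 to 0.949), 0.890 for pairs on the same slide and 0.895 for pairs on different slides. For what is left of single autosomal probes after subtracting each clone's running median over 51 probes, without those further than 1.5 from it, the mean r was 0.695 on the same slide and 0.526 on different slides, but B11 had 0.776 to 0.843 with the 3 clones of the other slide and 0.448 and 0.498 with the other clones of its own. After subtracting the mean profile the mean r was -0.193, against the -0.20 that subtraction alone gives, and was highest for B11 with E7 (0.171). F1 with E2 (0.155) and C5 with B11 (0.148) came near this. Within the set of G10, F1 and E2, G10 had 0.092 with E2 but -0.513 with F1, so this measure does not group the whole set.

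**Figure D4:**
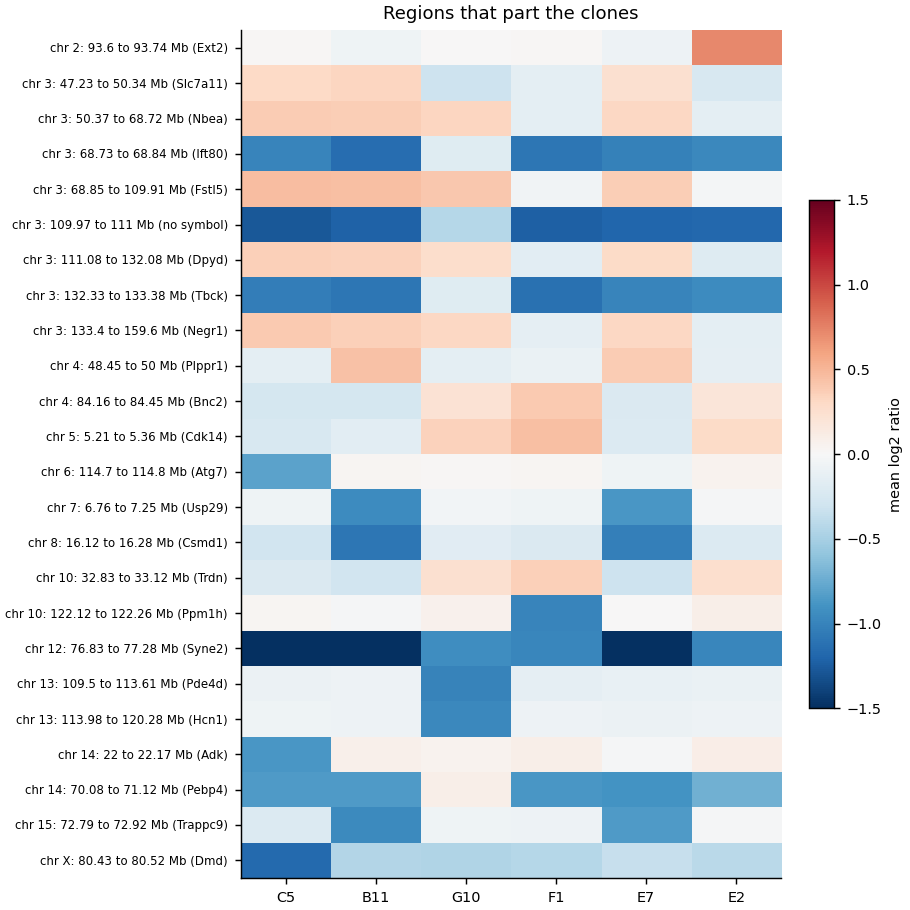
Mean log2 ratio (colour) of each clone (columns) in regions that part the clones by a gap (lines, named by position and the gene with most probes); the colour scale ends at -1.5 and 1.5. B11 and E7 are lower than the other clones over Usp29, Csmd1 and Trappc9.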

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

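All results here were found by asking whether the highest or lowest of the 6 clones lay further from its nearest neighbour than the others' range allows (gap over range, Dixon). Of 79 genes, chromosomes, loci and shares 6 met this, while chance gives about 1 in 20. Of 50 regions taken for their mean, length or list members 3 met it, and of 35 regions chosen because clones differ in them 13 did, which that choice favours. Each clone has 1 array, so no biological explanation was tested for these results.

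B11 stood apart for Notch1, a receptor of T-cell development (0.675), and for chromosome 2 from 24.22 to 39.71 Mb (0.791) and from 3.01 to 73.06 Mb (0.791), which in B11 lacked the gain of the other clones. G10 stood apart for Tet2 (0.857), whose region on chromosome 3 was less far down in it than in the other clones (0.847 from 132.2 to 133.4 Mb and 0.818 from 132.3 to 133.4 Mb). G10 was also less far down on chromosome 3 from 68.73 to 68.84 Mb with the ciliary gene Ift80 (0.820) and from 110 to 111 Mb (0.891), and kept chromosome 14 from 70.08 to 71.12 Mb (0.825). On chromosome 13 G10 was higher from 83.75 to 109.5 Mb (0.925) and lower from 109.5 to 120.3 Mb (0.949).

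C5 stood apart for the chromatin gene Ezh2, which was higher (0.655), and was lower on chromosome 12 from 21.54 to 51.71 Mb (0.980), in Atg7 on chromosome 6 (0.871), in Adk on chromosome 14 (0.884) and in Dmd on the X chromosome (0.864). F1 was higher for Cd86 (0.642) and for the median of chromosome 14 (0.660), and lower in Ppm1h on chromosome 10 (0.903). E2 had the lowest gained share of the autosomes (0.728) and was higher in Ext2 on chromosome 2 (0.883). E7 was lower on chromosome 2 from 151.7 to 156.7 Mb (0.718), at 0.56 against 0.64 to 0.67 in the other 5 clones, but E7 was the lowest clone in 35 of the 48 gains of the mean profile, so this is not particular to the region.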

How the results depend on the processing

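The base composition and background floor settings, and the receptor loci and X chromosome under every setting, were added after seeing the data. Genes with 1 or more probes gave 5219 gains and 3024 losses, and with 5 or more probes 1103 gains, because other numbers of genes were tested. A threshold of 0.15 gave 2108 lost genes, an altered share of 50.87%, a gained share of 20.51% and a lost share of 30.36%, and 0.4 gave 792 lost genes and shares of 17.41%, 12.15% and 5.26%, by construction. Loess gave an altered share of 29.74%, a lost share of 12.21% and an X ratio of -0.944. Removing the base composition trend gave an altered share of 30.08% and a lost share of 11.18%, an immunoglobulin heavy locus of -0.253, a kappa locus of 0.424 and an X ratio of -1.004. Mode centring left 0 chromosomes passing the exact permutation test and an X ratio of -1.015. Divergent segments numbered 100 with normexp, 241 and 95 with penalties of 20 and 80, and 34 in bins of 1 Mb. Normexp gave -0.513, -0.348 and -0.147 for the T-cell receptor alpha/delta, beta and gamma loci and -0.939 for X. Only bright probes gave -0.361, 0.146 (reversed) and -0.003, since they leave out dim clone probes, and the background floor gave -1.218, -1.075 and -0.331, by construction. For the loess, base composition, mode and normexp values the cause was not tested. Leaving out each clone gave 1872 to 1990 gained genes, 1198 to 1369 lost genes, altered shares of 33.83% to 35.77% and 110 to 144 divergent segments. Slide as a term gave 1922 gains and 1272 losses. Of 347 values of named genes 341 kept direction and call and 6 lost the call (Akap8l, Cd4, Ifnar2 and Tgfb2), and of 128 values of gene lists 128 kept theirs. Correction for 50 kb base composition was not run, since no genome of this build was used here. Chromosome tests without 1 clone or within 1 slide cannot pass.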

Other observations

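All tests in this part were chosen after the result was seen.

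All clones lacked most signal in 5 pieces of the T-cell receptor alpha/delta and beta loci, which make up 0.108% of the autosomes but hold 5 of the 16 autosomal segments at or below -2. Rearranged loci in the reference T lymphocytes would lower the reference and so raise the ratio, yet the clone with the highest level, clone signals raised to the background floor, was at -1.76. Probes that give no signal with any DNA are argued against by the reference signal, which was 1.58 log2 units under the autosomal median (-1.58) and well above background on all arrays for 98.7% of these probes, while the clone signal was at -5.54. Receptor rearrangement in a cell from which all 6 clones descend stays open and may explain the pieces, and the lowest segment of the immunoglobulin loci, at -0.54, showed no such loss there. Whether the myeloid line's ancestor had rearranged these loci was not tested otherwise.

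E7 lay between F1 and the other 4 clones on chromosome 16. On chromosome 14 from 77.93 to 125.2 Mb E7 (-0.04) also lay between F1 (0.25) and the other 4 (-0.16 to -0.23). The tests below were not run on that part of chromosome 14. F1 DNA mixed into E7 is argued against by the Syne2 to Esr2 interval, where E7 was at -3.47 with clone signals raised to the floor and a mixture would give -2.76. A weaker response of the E7 array is argued against by the other 7 of the 8 longest losses, where E7 had 0.974 ± 0.061 of the other clones' ratio, against 0.601 on chromosome 16. In gains E7 was weaker, the lowest clone in 35 of 48, with a median of 0.916 of the other clones' ratio over the 47 gains outside chromosome 16, but the lowest of these was 0.835. An extra chromosome 16 in part of the E7 cells may explain the pattern on that chromosome, but not the one on chromosome 14. The estimated share of cells was 0.313 from the lost piece and 0.270 from the rest, a ratio of 1.159. The same estimate gave F1 0.726 and 0.797, a ratio of 0.911, so F1 DNA mixed into E7 would also give similar shares. The ratio therefore does not tell a gain in part of the cells from a mixture.

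Several chromosomes part the clones in the same way: G10, F1 and E2 from C5, B11 and E7 on 5 chromosomes, and B11 and E7 from the rest on 4, by a gap set after looking at the values. On chromosome 3 the split of G10, F1 and E2 rests on 1 piece, from 47.23 to 50.34 Mb (-0.31, -0.15 and -0.24). From 50.37 to 68.72 Mb F1 and E2 stayed at -0.14, but G10 lay at 0.32. G10 thus does not share the extent of the change of F1 and E2 there, and the counts below include this piece. Slide is argued against, since the number of splits that equal the 2 slides was 0. The number along the order of the arrays' probe scatter was 0 too. This argues against scatter for the split of G10, F1 and E2, with scatters of 0.341, 0.127 and 0.349. B11 (0.243) and E7 (0.233) lie together in the middle of that order. The count could not take a split of these clones from the rest, so it does not decide on scatter there. With a gap of 0.35, 0 of 45 pairs of splits were incompatible with 1 branching order of the clones (29.3 in the mean of permutations, permutation p = 0.0001, the smallest the permutations can give), and with a gap of 0.5 it was 0 of 6 (mean 3.4, permutation p = 0.0189). With a gap of 0.25 it was 10 of 66 (mean 43.1, permutation p = 0.0001), and in each of the 10 pairs 1 member was the same split, B11 and G10 from the rest on chromosome 2. The splits thus conflict less than permuted clone labels at each gap. But only 3 different splits occurred at the gap of 0.35, 2 at 0.5 and 4 at 0.25, and equal splits cannot conflict. The permutations drew each split by itself, so their p-values in part measure that the same splits recur. They cannot decide whether 1 branching order holds for all splits, and the split of B11 and G10 from the rest keeps this open as well.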
